A study of Mus musculus with 6 samples.

How the data were processed

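RNA was measured by polyA sequencing in 6 mouse libraries of sorted Lewis lung carcinoma cells, 3 with a scrambled guide RNA and 3 with a Jag2 guide RNA. The authors deposited whole-number counts per gene and library, in 1 table of 55334 versioned Ensembl gene IDs. STAR 2.7.7a and HTSeq 0.11.2 are named in the submitters' processing notes, without their settings. The genome build, the annotation release, the strand setting and any read filter are not given in the sources used here. How reads over several genes or several places were counted is likewise not given, so paralogs, pseudogenes and overlapping or antisense genes can share or lose reads.

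Columns were tied to groups by their names. The Scramble columns carry the sample titles' numbers. The JAG2KO columns are numbered 2 to 4 whereas the titles run from 1 to 3, so each was used as a JAG2KO library without a replicate number and is called here by its column name. Of the gene IDs, 55154 matched a symbol by stable ID and 54587 also by version; the 180 others held 0.00193% of all counts. Coordinates and exon overlaps come from GENCODE M21 on GRCm38 and may differ from the annotation the authors counted on. For a symbol with several IDs, the ID with the most counts stood for it in the gene lists.

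Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), TMM factors were applied, and the 2 groups were compared by the quasi-likelihood F test with 4 residual degrees of freedom and Benjamini-Hochberg adjustment, called under 0.05. CPM values use TMM-scaled library sizes, and errors are SDs over 3 libraries. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Library totals and the CPM that 3 counts are worth (from 0.068 in Scramble1 to 0.0811 in JagKO2) set the precision for low genes. Where a group held 1 to 3 counts in all, the ratio of group counts is given with an exact 95% binomial interval, which covers counting error only. Within groups, library pairs differed by a chi-square of 12.2 to 31 per degree of freedom over genes with at least 20 counts, well above sampling noise, so no library was treated as a repeat of another.

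30 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset correlation of 0.01, two-sided and adjusted over the lists. The rule names Jag2, then the 10 genes with the largest change in each direction among called genes with a mean CPM of at least 2 and no overlap between the groups, leaving out unnamed gene models, and then up to 3 called members with the smallest p of each list, or 1 member, with values only, where none was called. A gene that the rule names is not reported here. Alternatives were RLE factors, library totals alone, no filter, a filter of CPM 1 in 3 libraries, DESeq2 1.42.0, limma-voom, each library left out in turn and, for lists, an estimated correlation, voom weights and fry. Removal of per-library trends on GC content and longest-transcript length (natural splines, 5 degrees of freedom; 16038 of the tested genes had both values) was added after the data were seen.

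The procedures were tested on simulated data: counts for the real genes with the real means, library sizes and dispersions, with 200 genes changed, 3 libraries against 3, over 10 draws (raised from 1 after a first run, with no analysis setting changed) and 15615 to 15709 genes. edgeR recovered 62.6% of 1.5-fold, 62.7% of 2-fold and 90.7% of 4-fold changes, and 7.25% of its calls were unchanged genes, above the nominal 5%. For DESeq2 that share was 16.1% and for limma-voom 6.19%. The same 200 genes were changed in every draw, while 24.3% of tested genes were called in the data, so these shares may not carry over. In simulated counts with 1 list shifted, camera called that list with both correlations and 0 others. The simulated genes were drawn independently, so this test does not cover correlated genes. Trend removal took 1584 calls made by a simulated GC trend to 1.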

Results

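RNA was sequenced from tumour cells of the Lewis lung carcinoma line, a mouse lung cancer line. The cells carried green fluorescent protein (GFP) and either a scrambled guide RNA (Scramble) or a guide RNA against the Notch ligand gene Jag2 (JAG2KO). Per the labels they were grown as flank tumours and sorted as GFP-positive, CD45-negative, DAPI-negative cells, and each group had 3 libraries. Scramble replicates 1, 2 and 3 held 43907690, 43923565 and 39448304 counts. The JAG2KO libraries deposited as JagKO2, JagKO3 and JagKO4 held 37036772, 37751864 and 42914376. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these samples, which may be technical. The series concerns tumour-cell Jagged2 and the macrophages of the tumour; the comparison asks how the sorted tumour cells themselves differed.

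Libraries of a group resembled each other more than those of the other group. Log2 CPM correlated across genes, which are not independent replicates, at r = 0.985 to 0.987 within Scramble and 0.981 to 0.985 within JAG2KO. Across the groups r was 0.962 to 0.968. The first principal component held 55.2% of the variance and separated the groups. The second held 13.8% and set JagKO2 (39.5) apart from JagKO3 (-36.3).

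Jag2, the gene targeted by the guide RNA, had few counts in every library. This protein-coding gene (ENSMUSG00000002799.6) lies on the minus strand of chromosome 12, 112907819 to 112929776 in GRCm38. It measured 1.52, 1.1 and 1.02 CPM in Scramble replicates 1, 2 and 3. The JAG2KO libraries JagKO2, JagKO3 and JagKO4 had 0.514, 0.799 and 1.11 CPM, so the groups overlapped. The log2 fold change was -0.58 (SE 0.39, edgeR adjusted p = 0.318), and a difference in Jag2 RNA was not detectable at this depth. An edited gene can still be transcribed and reads over the guide's target were not analysed here, so this level neither checks nor contradicts the labels.

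Other Notch pathway genes differed in both directions (CPM values are means ± SD, n = 3). Among Notch ligands, receptors and processing genes, 8 of 35 tested genes were higher, 5 lower and 22 not past the edgeR threshold (adjusted over the list alone, 10 higher and 6 lower). Maml2, a coactivator of Notch transcription, rose from 15.1 ± 0.546 CPM in Scramble to 28.9 ± 1.23 CPM in JAG2KO. The receptor gene Notch2 measured 168 ± 11.6 CPM in Scramble and 269.9 ± 7.33 CPM in JAG2KO, and Notch4 rose with a log2 fold change of 1.41 (SE 0.20, edgeR adjusted p = 0.000306). Among Notch target genes, 4 of 14 tested genes were higher, 0 lower and 10 not past the edgeR threshold (adjusted over the list alone, 5 higher and 1 lower). Those that rose included Notch3 (log2 fold change 1.90, edgeR adjusted p = 0.000503), Hey1 (log2 fold change 2.87, edgeR adjusted p = 0.00871) and Hes1 (log2 fold change 0.63, edgeR adjusted p = 0.0154). In the same libraries the endothelial markers Vwf and Pecam1 had log2 fold changes of 1.78 and 1.17. The pericyte marker Rgs5 and Pdgfrb had 1.94 and 0.82, but Fap of the same list had -2.40. Of 13 endothelial markers, 6 were higher and 1 lower. They summed to 146 ± 1.59 CPM in Scramble and 144 ± 11.5 CPM in JAG2KO. Without Scramble replicate 3 the log2 fold change of Hey1 was 3.46. Hes1 lost its call without Scramble replicate 2 or JagKO4 (adjusted p = 0.0623 to 0.0796). Notch2 and Hey1 lie on chromosome 3, where 189 of 581 genes with a mean CPM of at least 2 rose and 30 fell. Their rise was not separated from a shift of neighbouring genes. The Notch ligand and receptor list had a camera adjusted p = 0.26, and adjusted p = 0.685 with an estimated correlation. The Notch target list had a camera adjusted p = 0.331, and adjusted p = 0.628 with an estimated correlation.

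Across the transcriptome, 1891 genes were higher and 2005 lower in JAG2KO, of 16049 tested (edgeR quasi-likelihood test). Together these were 24.3% of the tested genes. Changes of at least 2-fold made up 509 of the higher and 487 of the lower genes. The 3 CPM values of each group lay wholly apart for 3822 of the called genes. Over all tested genes that held for 40.3%, where chance gives 10%.

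Among the genes named by rule, the largest increases included genes almost silent in Scramble. Tmem26, a transmembrane protein gene (chromosome 10, 68723646 to 68782650), had 2 counts over Scramble and 1043 over JAG2KO, a ratio of 562-fold (95% counting interval 155 to 4646). Both Scramble counts were in replicate 3, and without it JAG2KO was at least 259-fold higher, against a floor of 3 counts over the group. Krt5, a basal keratin gene (chromosome 15, 101707070 to 101712898), went from 2 to 532 counts, a ratio of 287-fold (95% counting interval 79 to 2373). It measured 4.62 ± 3.03 CPM in JAG2KO with 8.11 CPM in JagKO2, and without JagKO2 the ratio was 182-fold (95% counting interval 49.9 to 1513). Its partner keratin gene Krt14 measured 0.22 ± 0.24 CPM in Scramble and 5.5 ± 2.3 CPM in JAG2KO, a log2 fold change of 4.59, or 5.81 without Scramble replicate 1. Krt5 and Krt14 are also on the fixed list of muscle, fat, skin and red cell markers. The signalling adaptor gene Grap2 measured 0.333 ± 0.143 CPM in Scramble and 15.7 ± 2.01 CPM in JAG2KO. The homeobox genes Dlx3 and Esx1 rose with log2 fold changes of 4.90 and 4.15 (edgeR adjusted p = 0.000151 and 6.52e-06). Dlx3 measured 0.134 ± 0.019 CPM in Scramble and 4.07 ± 3.21 CPM in JAG2KO, and without JagKO4 its log2 fold change was 4.06. Loxl2, a lysyl oxidase gene whose product cross-links collagen (chromosome 14, 69609068 to 69695834), measured 7.14 ± 1.86 CPM in Scramble and 129 ± 15.5 CPM in JAG2KO, with a log2 fold change of 4.18 (SE 0.16, edgeR adjusted p = 9.32e-09). Sfmbt2, Rftn1 and Kank1 rose with log2 fold changes of 4.57, 3.66 and 3.62 (edgeR adjusted p = 1.05e-05, 2.22e-07 and 4.88e-05). The value was 5.26 for Sfmbt2 without Scramble replicate 2 and 4.27 for Kank1 without Scramble replicate 1.

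The largest decreases included a gene near 0 in JAG2KO. Hoxa11, a homeobox gene on chromosome 6, 52242106 to 52245810, had 1132 counts over Scramble and 1 over JAG2KO, a Scramble to JAG2KO ratio of 1051-fold (95% counting interval 188 to 41533). The count was in JagKO2, and without that library JAG2KO was at least 240.3-fold lower, against the floor of 3 counts. Trim44 (chromosome 2, 102300119 to 102407828) measured 88.1 ± 2.59 CPM in Scramble and 2.36 ± 0.626 CPM in JAG2KO, with a log2 fold change of -5.23 (SE 0.14, edgeR adjusted p = 4.16e-10). The cell adhesion gene Cadm1 (chromosome 9, 47530173 to 47857637) measured 48.6 ± 3.86 CPM in Scramble and 1.03 ± 0.151 CPM in JAG2KO, with a log2 fold change of -5.56 (SE 0.13, edgeR adjusted p = 1.72e-10). Lingo3, the microtubule-associated protein gene Map2 and Whrn had log2 fold changes of -7.17, -5.75 and -5.67. The angiotensin receptor gene Agtr2, Ppp1r9a and Rgl3 had log2 fold changes of -5.66, -5.41 and -5.22, and all 6 passed the edgeR threshold. Whrn had a log2 fold change of -5.04 without JagKO4, and without JagKO3 its Scramble to JAG2KO ratio was 498-fold (95% counting interval 89.1 to 19679). The counts of Agtr2 in JAG2KO were all in JagKO4, and without it JAG2KO was at least 172-fold lower, while Rgl3 had a log2 fold change of -6.07 without JagKO3. Mid1-ps1 fell by 5.55 on the log2 scale, but it is annotated as a pseudogene and can share reads with Mid1, so its level is uncertain.

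Some named genes overlap the exons of other genes, and the strand setting of the counting is not given in the sources used here, so their levels are uncertain. Opposite-strand genes overlap Hoxa11 (Hoxa11os), Ciita (Dexi) and mt-Nd6 (mt-Nd5). Opposite-strand gene models also overlap Krt5, Loxl2, Map2, Notch3, Usp18, Icam1, Irf1, Nlrc5, Krt8, Cd276, Tnfsf9, Hhip and Hmgcs1. Small same-strand models overlap Maml2, Notch2, Pdia4 and Loxl2. The Ifit, Oas, H2 and haemoglobin genes named here have close copies that can share reads.

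**Figure D1:**
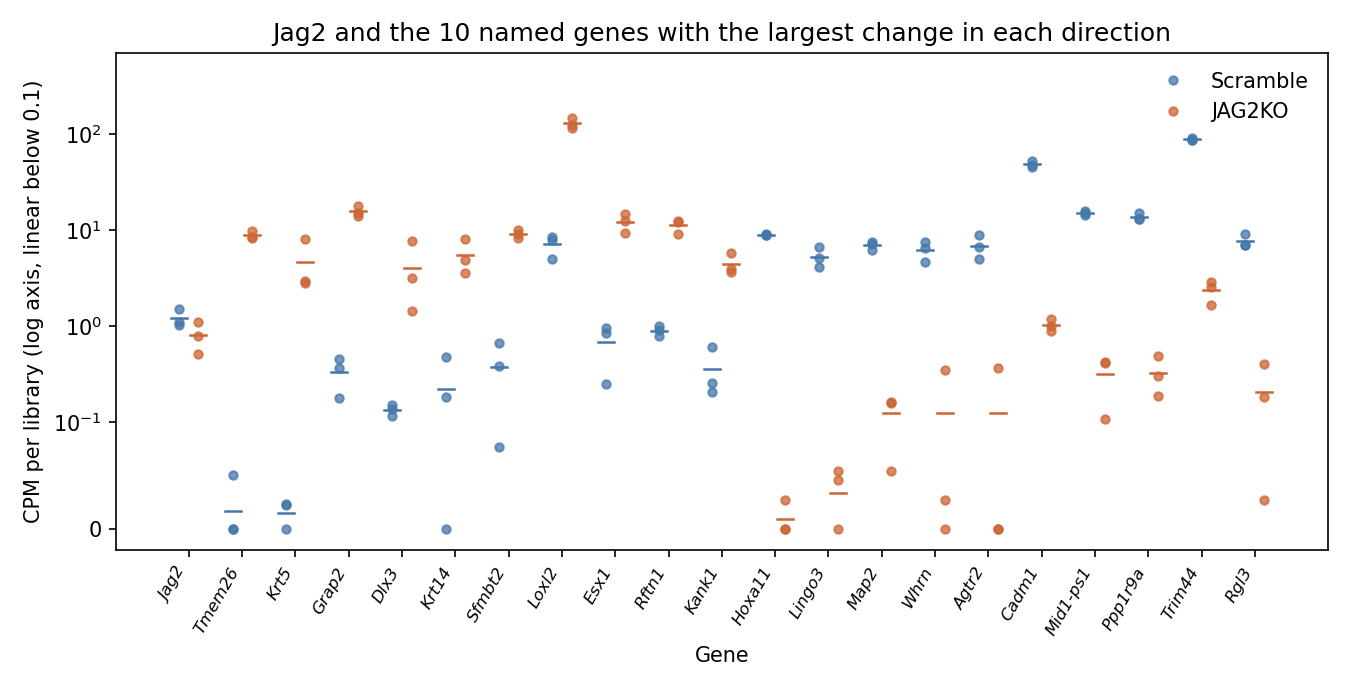
CPM of Jag2 and the 20 named genes with the largest changes, with 1 point per library, short lines at group means and a log axis that is linear below 0.1 CPM. Jag2 overlapped between the groups, while Loxl2 averaged 7.14 CPM in Scramble and 129 CPM in JAG2KO.

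Of 30 gene lists, 7 were called higher and 6 lower by camera with a preset correlation. With an estimated correlation 0 lists were called, 2 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 13. Other ways to part the 6 libraries into 3 and 3 gave up to 12 called lists, against 13 for the real groups. Those ways mix libraries of both groups on each side and keep part of the group difference, so 12 is not a chance level. Without Scramble replicate 3, 4 lists were called higher.

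Type I interferon-stimulated genes were lower in JAG2KO, with a median log2 fold change of -0.97. Of them, 0 of 35 tested genes were higher, 27 lower and 8 not past the edgeR threshold (adjusted over the list alone, 1 higher and 27 lower). Usp18, a negative regulator of interferon signalling, measured 11.6 ± 1.39 CPM in Scramble and 2.83 ± 0.653 CPM in JAG2KO, with a log2 fold change of -2.03 (SE 0.19, edgeR adjusted p = 1.61e-05). The antiviral genes Ifit1 and Oas3 fell by 2.09 and 1.78 on the log2 scale (edgeR adjusted p = 2.3e-05 and 4.87e-05). Usp18, Ifit1 and Oas3 lie on chromosomes 6, 19 and 5. Of genes with a mean CPM of at least 2 there, 86, 31 and 74 rose and 168, 129 and 144 fell. The fall of these 3 genes was not separated from shifts of neighbouring genes. The type I interferon list had a camera adjusted p = 1.5e-10, and adjusted p = 0.628 with an estimated correlation. Among interferon-gamma response genes, 7 of 28 tested genes were higher, 1 lower and 20 not past the edgeR threshold (adjusted over the list alone, 8 higher and 1 lower). The adhesion gene Icam1 rose from 2.1 ± 1.18 CPM in Scramble to 15.7 ± 2.37 CPM in JAG2KO. The transcription factor gene Irf1 had a log2 fold change of 0.46 and the tRNA synthetase gene Wars one of -0.34 (edgeR adjusted p = 0.0032 and 0.00299). The interferon-gamma list had a camera adjusted p = 0.0471, and adjusted p = 0.742 with an estimated correlation. The interferon-gamma call ended without a low-count filter, Scramble replicate 1, Scramble replicate 3, JagKO2 or JagKO3, and with RLE factors, the stricter filter or fry (adjusted p = 0.0511 to 0.675, range over all alternatives 0.000708 to 0.742). Macrophage markers summed to 141 ± 12.3 CPM in Scramble and 187 ± 14.1 CPM in JAG2KO.

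Some antigen presentation genes were higher and a few lower. Among MHC class I presentation genes, 5 of 23 tested genes were higher, 2 lower and 16 not past the edgeR threshold (adjusted over the list alone, 6 higher and 2 lower). Nlrc5, a transactivator of class I genes, measured 28.2 ± 2.94 CPM in Scramble and 50.4 ± 5.35 CPM in JAG2KO, with a log2 fold change of 0.84 (SE 0.10, edgeR adjusted p = 0.000107). The class I heavy chain gene H2-K1 measured 318 ± 42.2 CPM in Scramble and 515 ± 66.6 CPM in JAG2KO. Calr, an endoplasmic reticulum chaperone gene, fell by 0.43 on the log2 scale (edgeR adjusted p = 0.00096). The MHC class I list had a camera adjusted p = 0.347, and adjusted p = 0.866 with an estimated correlation. The MHC class I list passed without JagKO4 (adjusted p = 0.0359, range over all alternatives 0.0359 to 0.866), and its direction turned to lower without JagKO2 (adjusted p = 0.776). Among MHC class II genes, 2 of 8 tested genes were higher, 0 lower and 6 not past the edgeR threshold (adjusted over the list alone, 2 higher and 0 lower). The class II transactivator gene Ciita measured 0.139 ± 0.0957 CPM in Scramble and 0.798 ± 0.359 CPM in JAG2KO, and the protease gene Ctss 6.02 ± 1.6 CPM in Scramble and 10.2 ± 1.75 CPM in JAG2KO. The MHC class II list had a camera adjusted p = 0.0406, and adjusted p = 0.685 with an estimated correlation. The MHC class II call ended without Scramble replicate 2, Scramble replicate 3 or JagKO2, and with the stricter filter or fry (adjusted p = 0.0745 to 0.205, range over all alternatives 0.00664 to 0.685). Ciita lost its call without Scramble replicate 2, Scramble replicate 3 or JagKO2 (adjusted p = 0.0559 to 0.0597), and Ctss without Scramble replicate 2 or Scramble replicate 3 (adjusted p = 0.0657 to 0.0673). Ciita had a log2 fold change of 2.48, or 3.20 without Scramble replicate 1. Ctss lies on chromosome 3, where 189 of 581 genes with a mean CPM of at least 2 rose and 30 fell. Its rise was not separated from a shift of neighbouring genes. Macrophage markers summed to 141 ± 12.3 CPM in Scramble and 187 ± 14.1 CPM in JAG2KO in these libraries.

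**Figure D2:**
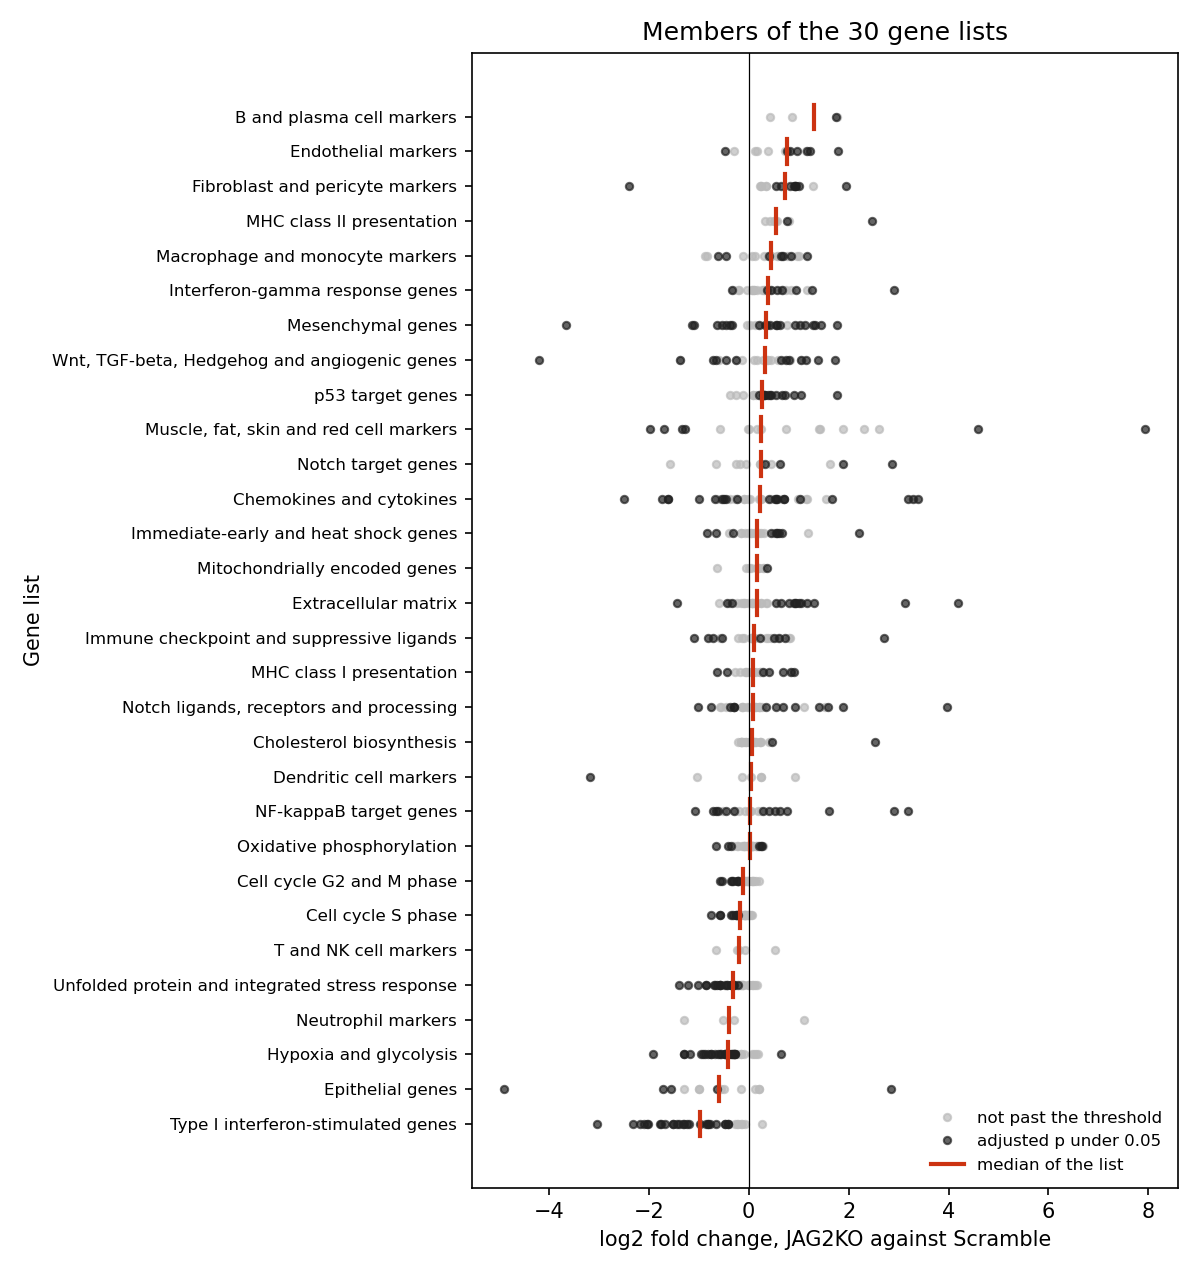
Log2 fold change (JAG2KO against Scramble) of each tested member of the 30 gene lists, dark where the edgeR adjusted p was under 0.05, with a red line at each list's median. The medians ran from -0.97 for type I interferon-stimulated genes to 1.31 for B and plasma cell markers, a list of 4 tested genes.

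Hypoxia and glycolysis genes were lower, with a median log2 fold change of -0.42. Of them, 1 of 35 tested genes were higher, 26 lower and 8 not past the edgeR threshold (adjusted over the list alone, 1 higher and 27 lower). Egln3 and Egln1, oxygen-sensing prolyl hydroxylase genes, both fell. Egln3 measured 248 ± 9.3 CPM in Scramble and 132 ± 6.34 CPM in JAG2KO, and Egln1 134 ± 1.58 CPM in Scramble and 79.8 ± 6.98 CPM in JAG2KO. The glycolytic enzyme gene Pgk1 measured 742 ± 11 CPM in Scramble and 404 ± 48.3 CPM in JAG2KO, with a log2 fold change of -0.88 (SE 0.08, edgeR adjusted p = 1.37e-05). Egln3, Egln1 and Pgk1 lie on chromosomes 12, 8 and X. Of genes with a mean CPM of at least 2 there, 30, 52 and 14 rose and 133, 117 and 92 fell. The fall of these named genes was not separated from shifts of neighbouring genes. The hypoxia list had a camera adjusted p = 4.89e-09, and adjusted p = 0.524 with an estimated correlation. Genes of the unfolded protein and integrated stress response were also lower, with a median of -0.31. Here 0 of 35 tested genes were higher, 21 lower and 14 not past the edgeR threshold (adjusted over the list alone, 1 higher and 24 lower). Mthfd2, a mitochondrial folate enzyme gene, and the asparagine synthetase gene Asns fell by 0.86 and 0.69 on the log2 scale (edgeR adjusted p = 3.79e-05 and 6.01e-05). The disulfide isomerase gene Pdia4 measured 333 ± 33.9 CPM in Scramble and 215 ± 10.4 CPM in JAG2KO. Mthfd2, Asns and Pdia4 all lie on chromosome 6, where 86 of 562 genes with a mean CPM of at least 2 rose and 168 fell. Asns lies there in a window of 15 neighbouring genes of which 1 rose and 11 fell. For these named genes a change of the stress response cannot be told apart from a shift of neighbouring genes. The stress response list had a camera adjusted p = 6.94e-06, and adjusted p = 0.628 with an estimated correlation.

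Some cell cycle genes were lower. Among S phase genes, 0 of 29 tested genes were higher, 9 lower and 20 not past the edgeR threshold (adjusted over the list alone, 0 higher and 9 lower). The ribonucleotide reductase gene Rrm2 measured 163 ± 2.97 CPM in Scramble and 109 ± 8.51 CPM in JAG2KO. The cyclin gene Ccne1 and the uracil glycosylase gene Ung fell by 0.75 and 0.57 on the log2 scale (edgeR adjusted p = 0.000314 and 0.00197). Rrm2, Ung and Ccne1 lie on chromosomes 12, 5 and 7. Of genes with a mean CPM of at least 2 there, 30, 74 and 126 rose and 133, 144 and 58 fell. The fall of Rrm2 and Ung was not separated from shifts of neighbouring genes. The S phase list had a camera adjusted p = 0.00184, and adjusted p = 0.592 with an estimated correlation. Among G2 and M phase genes, 0 of 30 tested genes were higher, 8 lower and 22 not past the edgeR threshold (adjusted over the list alone, 0 higher and 8 lower). Those that fell included Ccnb2 (log2 fold change -0.57, edgeR adjusted p = 9.03e-05), Anln (log2 fold change -0.35, edgeR adjusted p = 0.00214) and Ttk (log2 fold change -0.53, edgeR adjusted p = 0.00523). The G2 and M phase list had a camera adjusted p = 0.0238, and adjusted p = 0.628 with an estimated correlation. The G2 and M phase call ended without Scramble replicate 1 or JagKO2 (adjusted p = 0.0551 to 0.0772, range over all alternatives 0.0139 to 0.628). Among p53 target genes, 14 of 26 tested genes were higher, 0 lower and 12 not past the edgeR threshold (adjusted over the list alone, 16 higher and 0 lower). Trp53inp1, a p53-induced gene, measured 12.3 ± 1.1 CPM in Scramble and 41.7 ± 1.61 CPM in JAG2KO, with a log2 fold change of 1.76 (SE 0.09, edgeR adjusted p = 1.33e-07). The kinase gene Plk2 and the RNA-binding protein gene Zmat3 rose by 1.05 and 0.72 on the log2 scale (edgeR adjusted p = 5.75e-05 and 0.000118). Zmat3, Plk2 and Trp53inp1 lie on chromosomes 3, 13 and 4. Of genes with a mean CPM of at least 2 there, 189, 77 and 104 rose and 30, 39 and 121 fell. The rise of Zmat3 and Plk2 was not separated from shifts of neighbouring genes. The p53 target list had a camera adjusted p = 5.27e-05, and adjusted p = 0.524 with an estimated correlation.

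Extracellular matrix genes moved in both directions. Of them, 12 of 33 tested genes were higher, 3 lower and 18 not past the edgeR threshold (adjusted over the list alone, 14 higher and 4 lower). The collagen gene Col5a2 measured 24.9 ± 5.57 CPM in Scramble and 218 ± 40.4 CPM in JAG2KO, with a log2 fold change of 3.13 (SE 0.16, edgeR adjusted p = 9.99e-08). The thrombospondin gene Thbs2 measured 419 ± 49.2 CPM in Scramble and 155 ± 24.1 CPM in JAG2KO. The matrix list had a camera adjusted p = 0.0437, and adjusted p = 0.739 with an estimated correlation. The matrix call ended without Scramble replicate 1, Scramble replicate 3 or JagKO2, and with the stricter filter, fry or GC and length trends removed (adjusted p = 0.0503 to 0.232, range over all alternatives 0.0104 to 0.739). Fibroblast and pericyte markers, some of which are matrix genes in both lists, summed to 5114 ± 53.5 CPM in Scramble and 7817 ± 2011 CPM in JAG2KO.

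Mesenchymal genes also went both ways, and 14 of 28 tested genes were higher, 8 lower and 6 not past the edgeR threshold (adjusted over the list alone, 16 higher and 8 lower). The stromelysin gene Mmp3 measured 799 ± 145 CPM in Scramble and 63.1 ± 9.16 CPM in JAG2KO, with a log2 fold change of -3.66 (SE 0.14, edgeR adjusted p = 9.36e-09). The cadherin gene Cdh2 rose from 12.8 ± 1.59 CPM in Scramble to 43.3 ± 3.19 CPM in JAG2KO, and Tgfbi rose from 60.5 ± 1.71 CPM in Scramble to 115 ± 1.39 CPM in JAG2KO. In the same libraries 9 of 16 fibroblast and pericyte markers were higher, and these markers summed to 5114 ± 53.5 CPM in Scramble and 7817 ± 2011 CPM in JAG2KO, with 10126 CPM in JagKO2. The mesenchymal list had a camera adjusted p = 0.0528, and adjusted p = 0.524 with an estimated correlation. The mesenchymal list passed without a low-count filter, and with voom weights or fry (adjusted p = 0.0062 to 0.0356, range over all alternatives 0.0062 to 0.524). Among epithelial genes, 1 of 14 tested genes were higher, 4 lower and 9 not past the edgeR threshold (adjusted over the list alone, 2 higher and 5 lower). The keratin gene Krt8 measured 124 ± 4.6 CPM in Scramble and 4.13 ± 0.84 CPM in JAG2KO, with a log2 fold change of -4.90 (SE 0.12, edgeR adjusted p = 1.72e-10). The tight junction gene Ocln and the keratin gene Krt19 fell by 1.71 and 1.55 on the log2 scale (edgeR adjusted p = 6.08e-06 and 0.0117). The epithelial list had a camera adjusted p = 0.0327, and adjusted p = 0.628 with an estimated correlation. The epithelial call ended without a low-count filter, Scramble replicate 1, Scramble replicate 2, JagKO2 or JagKO3, and with voom weights (adjusted p = 0.0585 to 0.251, range over all alternatives 0.00537 to 0.628).

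Secreted immune mediators were split. Among chemokines and cytokines, 11 of 42 tested genes were higher, 10 lower and 21 not past the edgeR threshold (adjusted over the list alone, 15 higher and 11 lower). The neutrophil chemoattractant gene Cxcl2 measured 12.5 ± 2.05 CPM in Scramble and 114 ± 19.8 CPM in JAG2KO, with a log2 fold change of 3.19 (SE 0.14, edgeR adjusted p = 3e-08). The chemokine gene Cxcl12 measured 5.03 ± 3.19 CPM in Scramble and 48.5 ± 4.62 CPM in JAG2KO, with a log2 fold change of 3.28 (SE 0.30, edgeR adjusted p = 1.21e-05), or 3.92 without Scramble replicate 3. The granulocyte growth factor gene Csf3 fell by 2.50 on the log2 scale (edgeR adjusted p = 2.3e-05). In these libraries fibroblast and pericyte markers summed to 5114 ± 53.5 CPM in Scramble and 7817 ± 2011 CPM in JAG2KO. Macrophage markers summed to 141 ± 12.3 and 187 ± 14.1 CPM, and endothelial markers to 146 ± 1.59 and 144 ± 11.5 CPM, in the same order. The chemokine and cytokine list had a camera adjusted p = 0.524, and adjusted p = 0.686 with an estimated correlation. Among NF-kappaB target genes, 8 of 23 tested genes were higher, 6 lower and 9 not past the edgeR threshold (adjusted over the list alone, 8 higher and 6 lower). Cxcl2, Icam1 and the signalling adaptor gene Traf1 rose, and Traf1 measured 7.39 ± 0.871 CPM in Scramble and 22.4 ± 3.6 CPM in JAG2KO. The NF-kappaB list had a camera adjusted p = 0.524, and adjusted p = 0.866 with an estimated correlation, and its direction turned without JagKO3 (adjusted p = 0.979). Among immune checkpoint and suppressive ligand genes, 5 of 24 tested genes were higher, 4 lower and 15 not past the edgeR threshold (adjusted over the list alone, 6 higher and 4 lower). Cd276, an inhibitory B7 family gene, measured 64.4 ± 3.02 CPM in Scramble and 91.5 ± 17.7 CPM in JAG2KO, with a log2 fold change of 0.51 (SE 0.11, edgeR adjusted p = 0.00623). The T-cell costimulatory ligand gene Tnfsf9 and the adhesion gene Nectin3 fell by 0.81 and 0.53 on the log2 scale (edgeR adjusted p = 0.00493 and 0.000685). The checkpoint list had a camera adjusted p = 0.377, and adjusted p = 0.685 with an estimated correlation.

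Lists of other signalling and metabolic genes were not called. Among Wnt, TGF-beta, Hedgehog and angiogenic genes, 7 of 26 tested genes were higher, 6 lower and 13 not past the edgeR threshold (adjusted over the list alone, 9 higher and 6 lower). The Hedgehog inhibitor gene Hhip fell by 4.20 on the log2 scale, and the BMP-induced gene Id3 rose from 124 ± 19 CPM in Scramble to 256 ± 31.4 CPM in JAG2KO. The Wnt modulator gene Dkk2 measured 547 ± 14.8 CPM in Scramble and 332 ± 38 CPM in JAG2KO, with a log2 fold change of -0.72 (SE 0.08, edgeR adjusted p = 4.87e-05). The Wnt and related list had a camera adjusted p = 0.662, and adjusted p = 0.866 with an estimated correlation, and its direction turned with fry (adjusted p = 0.662). Among oxidative phosphorylation genes, 3 of 34 tested genes were higher, 3 lower and 28 not past the edgeR threshold (adjusted over the list alone, 1 higher and 3 lower). The cytochrome c gene Cycs measured 74.3 ± 3.18 CPM in Scramble and 47.3 ± 7.36 CPM in JAG2KO. Ndufa4 and Ndufa5, respiratory chain genes, had log2 fold changes of -0.35 and -0.42 (edgeR adjusted p = 0.00305 and 0.0162). Ndufa5 lost its call without Scramble replicate 3 (adjusted p = 0.0754). The 3 lower genes, Cycs, Ndufa4 and Ndufa5, all lie on chromosome 6. There 86 of 562 genes with a mean CPM of at least 2 rose and 168 fell, so their fall cannot be told apart from a shift of neighbouring genes. The oxidative phosphorylation list had a camera adjusted p = 0.677, and adjusted p = 0.87 with an estimated correlation, and its direction turned without Scramble replicate 1 or JagKO2 (adjusted p = 0.93 and 0.906). Its median log2 fold change was 0.02 and camera's direction was higher, but the mean was -0.01. Among cholesterol biosynthesis genes, 2 of 22 tested genes were higher, 0 lower and 20 not past the edgeR threshold (adjusted over the list alone, 2 higher and 0 lower). The synthase gene Hmgcs1 measured 203 ± 26 CPM in Scramble and 281 ± 53.9 CPM in JAG2KO. Hmgcs1 lost its call without Scramble replicate 1, Scramble replicate 3 or JagKO3 (adjusted p = 0.0511 to 0.0773). The cholesterol list had a camera adjusted p = 0.524, and adjusted p = 0.87 with an estimated correlation, and its direction turned without Scramble replicate 1 or JagKO3 (adjusted p = 0.93 and 0.859).

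Genes that respond to dissociation and mitochondrial transcripts were measured as signs of sample handling. Among immediate-early and heat shock genes, 6 of 24 tested genes were higher, 3 lower and 15 not past the edgeR threshold (adjusted over the list alone, 10 higher and 4 lower). The nuclear receptor gene Nr4a1 measured 57.2 ± 16.6 CPM in Scramble and 263 ± 29.7 CPM in JAG2KO, with a log2 fold change of 2.20 (SE 0.16, edgeR adjusted p = 2.65e-06). Log2 fold changes were 0.57 for Egr1 and 0.67 for Btg2 (edgeR adjusted p = 0.000876 and 0.000953). The immediate-early list had a camera adjusted p = 0.187, and adjusted p = 0.739 with an estimated correlation. Among mitochondrially encoded genes, 1 of 12 tested genes were higher, 0 lower and 11 not past the edgeR threshold (adjusted over the list alone, 0 higher and 0 lower). The gene called was mt-Nd6 (38.1 ± 6.1 CPM in Scramble and 48.8 ± 1.56 CPM in JAG2KO), which overlaps mt-Nd5 and lost its call without Scramble replicate 2, Scramble replicate 3, JagKO3 or JagKO4 (adjusted p = 0.0566 to 0.0925). The mitochondrial list had a camera adjusted p = 0.253, and adjusted p = 0.813 with an estimated correlation. The mitochondrial list passed without Scramble replicate 2 (adjusted p = 0.0315, range over all alternatives 0.0315 to 0.813).

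Markers of other cell types changed in part. Among endothelial markers, 6 of 13 tested genes were higher, 1 lower and 6 not past the edgeR threshold (adjusted over the list alone, 8 higher and 1 lower). Those that rose included Vwf (log2 fold change 1.78, edgeR adjusted p = 0.000248), Cdh5 (log2 fold change 0.82, edgeR adjusted p = 0.000999) and Pecam1 (log2 fold change 1.17, edgeR adjusted p = 0.00134). The endothelial list had a camera adjusted p = 0.0065, and adjusted p = 0.524 with an estimated correlation. Their median log2 fold change was 0.77, but they summed to 146 ± 1.59 CPM in Scramble and 144 ± 11.5 CPM in JAG2KO. Eng, chosen after its values were seen, has the highest level of them and measured 101 ± 3.18 CPM in Scramble and 73.4 ± 11 CPM in JAG2KO. Among fibroblast and pericyte markers, 9 of 16 tested genes were higher, 1 lower and 6 not past the edgeR threshold (adjusted over the list alone, 12 higher and 1 lower). The pericyte gene Rgs5 measured 7.55 ± 1.35 CPM in Scramble and 29 ± 8.87 CPM in JAG2KO, and the growth factor receptor gene Pdgfrb 26.9 ± 3.54 CPM in Scramble and 47.6 ± 6.6 CPM in JAG2KO. The fibroblast activation protein gene Fap fell from 19 ± 1.11 CPM in Scramble to 3.61 ± 1.14 CPM in JAG2KO. The fibroblast and pericyte list had a camera adjusted p = 0.0021, and adjusted p = 0.628 with an estimated correlation. The fibroblast and pericyte call ended with fry (adjusted p = 0.1, range over all alternatives 0.000111 to 0.628). Among macrophage and monocyte markers, 5 of 24 tested genes were higher, 2 lower and 17 not past the edgeR threshold (adjusted over the list alone, 9 higher and 2 lower). The lysozyme gene Lyz2 and the complement gene C1qb rose by 1.16 and 0.84 on the log2 scale, and the cathepsin gene Ctsc fell by 0.61 (edgeR adjusted p = 1.98e-05, 0.00359 and 0.000641). The macrophage and monocyte list had a camera adjusted p = 0.0197, and adjusted p = 0.628 with an estimated correlation. The macrophage and monocyte call ended without JagKO3, and with fry (adjusted p = 0.0617 to 0.1, range over all alternatives 0.00105 to 0.628).

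**Figure D3:**
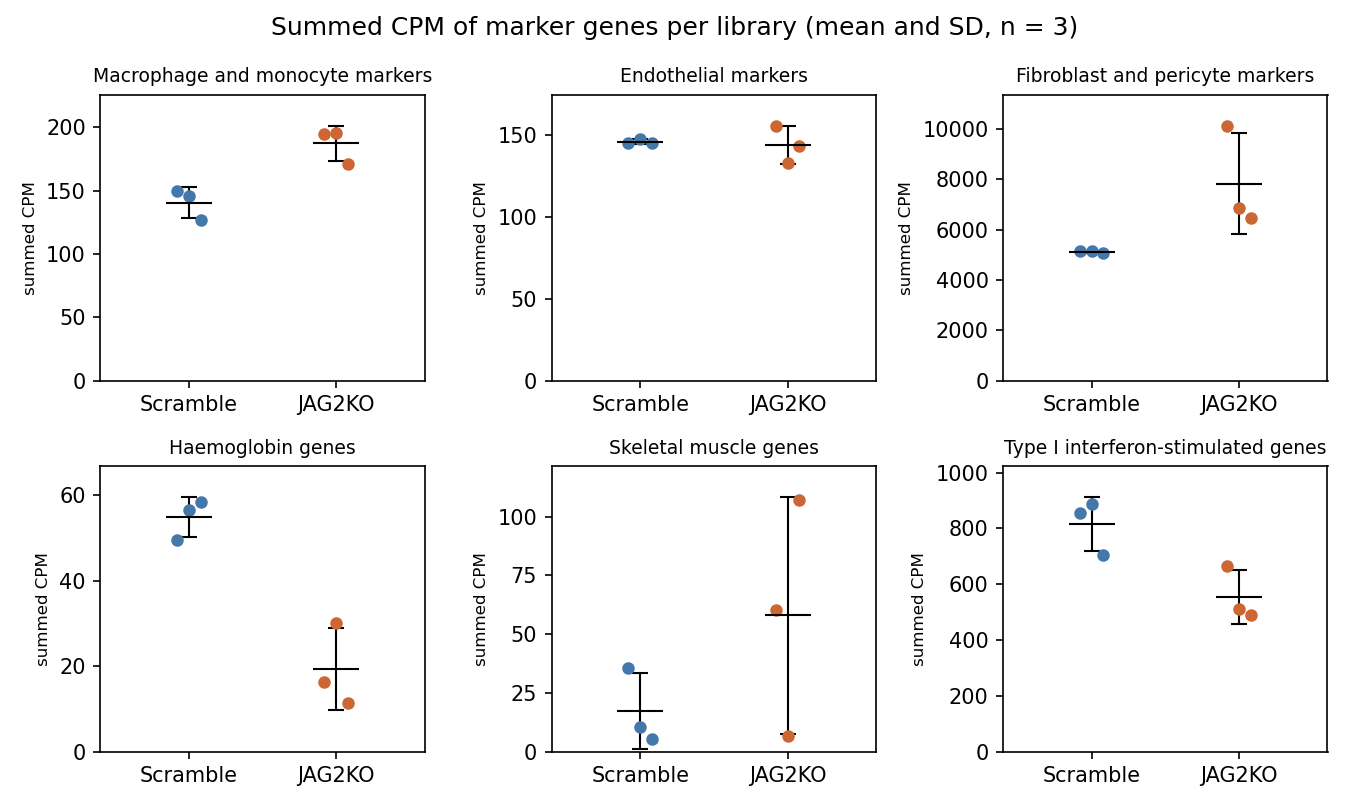
Summed CPM of marker genes in each library, with 1 point per library and horizontal lines with bars at the group mean and SD (n = 3); every axis starts at 0. Macrophage markers summed to 141 ± 12.3 CPM in Scramble and 187 ± 14.1 CPM in JAG2KO, and skeletal muscle genes ranged in JAG2KO from 6.65 to 107 CPM.

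Haemoglobin genes were lower, and lymphoid and neutrophil markers had low levels. Among muscle, fat, skin and red cell markers, 2 of 17 tested genes were higher, 4 lower and 11 not past the edgeR threshold (adjusted over the list alone, 2 higher and 4 lower). Krt5 and Krt14 were the higher ones, and Hba-a1, Hba-a2, Hbb-bs and Hbb-bt the lower ones, with Hbb-bs at 27.4 ± 3.08 CPM in Scramble and 8.49 ± 4.64 CPM in JAG2KO. Hbb-bt lost its call without Scramble replicate 3 (adjusted p = 0.0602). Haemoglobin genes summed to 54.9 ± 4.71 CPM in Scramble and 19.4 ± 9.67 CPM in JAG2KO. The muscle, fat, skin and red cell list had a camera adjusted p = 0.755, and adjusted p = 0.866 with an estimated correlation, and its direction turned without Scramble replicate 3 or JagKO4 (adjusted p = 0.974 and 0.928). Among B and plasma cell markers, 1 of 4 tested genes were higher, 0 lower and 3 not past the edgeR threshold (adjusted over the list alone, 2 higher and 0 lower). The immunoglobulin heavy chain gene Ighm measured 5.38 ± 0.985 CPM in Scramble and 18.1 ± 6.07 CPM in JAG2KO. The B and plasma cell list had a camera adjusted p = 0.187, and adjusted p = 0.628 with an estimated correlation. The B and plasma cell list passed without JagKO2, and with fry (adjusted p = 0.027 to 0.0474, range over all alternatives 0.027 to 0.628). Among dendritic cell markers, 0 of 7 tested genes were higher, 1 lower and 6 not past the edgeR threshold (adjusted over the list alone, 0 higher and 1 lower). The lower one was Fscn1, an actin-bundling gene, with 611 ± 23.4 CPM in Scramble and 68.1 ± 6.42 CPM in JAG2KO. The dendritic cell list had a camera adjusted p = 0.643, and adjusted p = 0.866 with an estimated correlation. Its median log2 fold change was 0.05, but the mean was -0.41 and camera's direction was lower, turning without the low-count filter (adjusted p = 0.649). Among neutrophil markers, 0 of 4 tested genes were higher, 0 lower and 4 not past the edgeR threshold (adjusted over the list alone, 0 higher and 0 lower); 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. Clec4d measured 0.63 ± 0.386 CPM in Scramble and 1.36 ± 0.243 CPM in JAG2KO and was called without Scramble replicate 3 (adjusted p = 0.0243). The neutrophil list had a camera adjusted p = 0.524, and adjusted p = 0.742 with an estimated correlation. Among T and NK cell markers, 0 of 5 tested genes were higher, 0 lower and 5 not past the edgeR threshold (adjusted over the list alone, 0 higher and 0 lower); 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 and 0. Trac measured 0.38 ± 0.0903 CPM in Scramble and 0.239 ± 0.0503 CPM in JAG2KO. The T and NK cell list had a camera adjusted p = 0.524, and adjusted p = 0.866 with an estimated correlation, and its direction turned without Scramble replicate 1, Scramble replicate 3 or JagKO4 (adjusted p = 0.821, 0.914 and 0.633).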

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

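No paired analysis was possible because the JAG2KO columns are numbered 2 to 4 and the labels 1 to 3, so no column's number could be tied to a label. Removal of GC and length trends was chosen after the data were seen; the other alternatives were fixed before. Counts of called genes stayed within 1.5 times of the reported ones, 1899 to 2301 higher and 1865 to 2105 lower with all libraries, and 1356 to 1926 higher and 1349 to 2093 lower with 1 library left out. Between 66.8% and 98.7% of the reported calls were shared, none with the opposite sign. Jag2 stayed below the threshold in every alternative, with log2 fold changes from -0.88 to -0.34. Of the 93 other named genes, none changed sign, and none changed its call with all libraries kept, where the gene was still tested. Without Scramble replicate 3, 5 lost and 1 gained a call, and the other left-out libraries ended 1 to 4 calls. Low counts limited Jag2 and most lymphoid markers.

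Gene list calls depended more on the settings. With an estimated correlation 0 lists were higher and 0 lower, with adjusted p from 0.524 to 0.87. The stricter filter left 4 higher lists, and removed every tested T and NK marker. Leaving out 1 library gave 4 to 8 higher lists, the fewest without Scramble replicate 3, and 4 to 6 lower lists. The lists of type I interferon, hypoxia, stress response, S phase, p53, endothelial and fibroblast genes kept their calls in each of these. With fry, which does not compare a list with other genes, 5 lists not called as reported passed. They were the Notch ligand and receptor (0.0199), chemokine and cytokine (0.0124), dendritic cell (0.00691), mesenchymal (0.0062) and B and plasma cell (0.027) lists. Another 5 lists lost their calls with fry, those of MHC class II (0.172), interferon-gamma (0.336), matrix (0.1), macrophage (0.1) and fibroblast (0.1) genes. Lists not called as reported changed sign in some alternatives: MHC class I genes without JagKO2 (0.776; range with 1 library left out 0.0359 to 0.861), NF-kappaB genes without JagKO3 (0.979; range with 1 library left out 0.333 to 0.979), oxidative phosphorylation genes without Scramble replicate 1 or JagKO2 (0.93, 0.906; range with 1 library left out 0.402 to 0.93), cholesterol genes without Scramble replicate 1 or JagKO3 (0.93, 0.859; range with 1 library left out 0.104 to 0.93), Wnt and related genes with fry (0.662), T and NK cell genes without Scramble replicate 1, Scramble replicate 3 or JagKO4 (0.821, 0.914, 0.633; range with 1 library left out 0.223 to 0.914), dendritic cell genes without the filter (0.649), muscle, fat, skin and red cell genes without Scramble replicate 3 or JagKO4 (0.974, 0.928; range with 1 library left out 0.527 to 0.974). The values in brackets are adjusted p. The cause was not tested.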

Other observations

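The gene families described here, and the tests of chromosome segments and of macrophage, haemoglobin and endothelial markers, were chosen after the result was seen. Of 11 tested Hoxa homeobox genes, 8 rose and 1, Hoxa11, fell, and of 8 Hoxb genes 0 rose and 6 fell. Of 6 Hoxc genes 0 rose and 1 fell, and of 6 Hoxd genes 1 rose and 0 fell. The Hoxc call ended (0 lower) without Scramble replicate 1, Scramble replicate 2 or JagKO3. The Hoxd call ended (0 higher) without Scramble replicate 2, Scramble replicate 3, JagKO2 or JagKO4. Hoxa5 measured 11.2 ± 3.13 CPM in Scramble and 29.7 ± 4.2 CPM in JAG2KO, and Hoxb7 measured 5.13 ± 0.843 CPM in Scramble and 0.596 ± 0.18 CPM in JAG2KO. Genes of a cluster are neighbours, so most higher calls came from the Hoxa locus on chromosome 6 and most lower calls from the Hoxb locus on chromosome 11. A difference between clusters was not tested.

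Gene families examined numbered 15, and the 6 described here were picked after their values were seen. Of 15 matrix metalloproteinase genes, 6 fell and 5 rose, or 3 rose without Scramble replicate 1, Scramble replicate 3 or JagKO4. The 6 that fell (Mmp1a, Mmp1b, Mmp3, Mmp10, Mmp12 and Mmp13) lie in a single cluster on chromosome 9, so they are not independent of each other. The stromelysin gene Mmp10 measured 27.1 ± 5.88 CPM in Scramble and 2.4 ± 1.04 CPM in JAG2KO, and the collagenase gene Mmp13 24.4 ± 6.36 CPM in Scramble and 3.51 ± 0.826 CPM in JAG2KO. The gelatinase gene Mmp9 rose from 14 ± 2.05 CPM in Scramble to 34.3 ± 6.96 CPM in JAG2KO. Of 12 Adamts protease genes 6 rose and 2 fell, and of 29 collagen genes 13 rose and 2 fell, or 1 fell without each library other than JagKO4. Several of these collagens are also in the matrix list. Fibroblast and pericyte markers summed to 5114 ± 53.5 CPM in Scramble and 7817 ± 2011 CPM in JAG2KO in the same libraries, with 10126 CPM in JagKO2, and these markers include the collagens Col1a1, Col1a2 and Col3a1. Of 49 histone genes 0 rose and 5 fell, or 3 fell without Scramble replicate 3 and 7 without JagKO2. The share of histone genes that fell was no higher than over all tested genes, where 2005 of 16049 fell. Of 27 integrin genes 2 rose and 7 fell, or 4 fell without JagKO4 and 1 rose without Scramble replicate 1, JagKO3 or JagKO4. The counts of these 6 families were equal with RLE factors and with library totals, and no test of enrichment is given because neighbouring genes shifted together.

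Called genes were counted in all 10 ways to part the 6 libraries into 3 and 3. The real split called 3896 genes and the highest other split 0, so 1 split, the real one, reached that count. In the other splits edgeR gave at most 506 genes at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 at most 19. For gene lists the real split called 13 and the highest other split 12, so again 1 split reached it. 10 splits are too few for a share under 0.05. Each other split has libraries of both groups on both sides. It keeps only part of the group difference in its contrast, and the rest adds to its spread and lowers its gene calls. The counts of the other splits therefore do not give the level expected by chance.

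Neighbouring genes shifted together along chromosomes, and the window of 15 neighbouring genes with the lowest median log2 fold change (-1.53, against -0.63 for the lowest on another chromosome and 0.81 for the highest) lay on chromosome 5, 5664829 to 9481825, where 11 fell and 0 rose, among them the drug efflux gene Abcb1b (315 ± 16.5 CPM in Scramble and 62.7 ± 2.81 CPM in JAG2KO) and the replication kinase subunit gene Dbf4 (232 ± 17 CPM in Scramble and 46.1 ± 2.49 CPM in JAG2KO). On chromosome 3, 189 genes rose and 30 fell, and on chromosome X 14 rose and 92 fell. A trend on GC content and length did not account for it: after its removal the rank correlation of fold changes of genes 5 to 10 Mb apart was 0.0853, against at most 0.00487 in 200 shuffled orders. Before removal the correlation was 0.0808, above that in shuffled orders (0.00549 at most) and in contrasts of 1 library with the others of its group (0.0162 at most), which restates the pattern and does not say what gave it. Gain or loss of chromosome segments between the injected cell populations and regulation of whole domains would both give this. They cannot be told apart because DNA was not measured. The changes of the named genes and lists were not separated from such shifts.

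The fall of 27 of 35 type I interferon-stimulated genes (adjusted p = 0.628 for the list with an estimated correlation) was weighed against 2 technical explanations. After removal of the GC and length trend the list's median log2 fold change was -0.92, against -0.97 before, which argues against that trend as the cause. Fewer macrophages in the JAG2KO libraries would lower macrophage markers, but their median was 0.45. Each JAG2KO library had a higher summed CPM of these markers than each Scramble library. Of the 24 markers, 5 were called higher and 2 lower, and Lyz2 alone went from 21.3 CPM in Scramble to 47.8 CPM in JAG2KO. Expression of these genes by the tumour cells was not separated from macrophage content, so fewer macrophages are not excluded. Shifts of neighbouring genes were not weighed for this list. The Jag2 guide and any other difference between the 2 injected cell populations stay open, and the design cannot separate them.

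Of the endothelial, fibroblast and macrophage markers, 6 of 13, 9 of 16 and 5 of 24 rose in JAG2KO, and the lists had adjusted p = 0.524, 0.628 and 0.628 with an estimated correlation. The endothelial markers summed to 146 ± 1.59 CPM in Scramble and 144 ± 11.5 CPM in JAG2KO. A lower share of tumour cells, with every other cell type carried over alike, would raise red cell genes too. The median log2 fold change of 4 haemoglobin genes was -1.52. In Scramble and JAG2KO, B and plasma cell markers summed to 8.06 and 22.9 CPM, and skeletal muscle genes to 17.3 and 58.1 CPM. Neutrophil markers summed to 9.41 and 8.06 CPM, T and NK markers to 2.5 and 2.35, and dendritic cell markers to 631 and 92.1, in that order. A lower share of tumour cells with unequal carry-over stays open. More endothelial cells passing the sort may account for the median of 0.77 of their markers, but expression of these genes by the tumour cells would give the same, and the 2 cannot be told apart without cell counts. The GFP gate would remove endothelial cells and the CD45 gate would remove macrophages, and Eng, the most abundant endothelial marker, measured 101 ± 3.18 CPM in Scramble and 73.4 ± 11 CPM in JAG2KO.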
